A study of Apis mellifera with 36 samples.

How the data were processed

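The series holds RNA sequencing of brain tissue from 36 individual honey bee workers (Apis mellifera). Per the labels' protocols, the dissected tissue held mostly the mushroom bodies, paired brain centres for learning and multisensory integration, and central brain. Each library came from a separate bee aged 7 days. The bees came from 2 colonies, each headed by a queen inseminated by a single drone, so that workers of one colony share the father's whole genome. Per the labels, bees were kept from emergence in dishes of 10, and each dish was tested with an intruder bee and with a queen larva in assays of 5 minutes, both repeated. Bees that attacked the intruder in both of its assays were called guards, bees that nursed the larva in both of its assays were called nurses, and bees that showed no overt response were called unresponsive. Each colony contributed 6 bees of each type, which gives 12 libraries per type and 18 per colony.

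Per the labels' protocols, libraries were made with a stranded poly(A) mRNA kit from 550 ng of RNA and sequenced for 101 cycles. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, SAMtools 0.1.19 and HTSeq, and the labels name the bee genome assembly and deformed wing virus (DWV), an RNA virus of bees, as mapping targets. The order and settings of those tools, the version of HTSeq and its strand option are not given in the sources used here. The deposited files hold whole-number read counts per gene that the authors did not normalize, one file per bee. Each file lists 15314 gene IDs and 5 summary rows that name no gene. The largest summary row, reads in no annotated gene, held 28.9% ± 0.534 (SD, n = 36) of the counted reads. The summary rows stayed out of library sizes and tests. The labels also give each library's total reads, reads mapped to the genome and reads mapped to DWV. DWV load was computed as DWV reads per 1000000 total reads (RPM) and used on the log10 scale.

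The files do not pair gene IDs with names, and 0 of the 15314 IDs matched the gene table at hand. Genes are therefore given by ID alone, no more than a pair per direction and comparison. The gene lists, the cell type markers and the genes to be reported in any case that were fixed before the data were examined could not be matched, so none of these was tested. Genes that share reads with a near-identical copy could not be recognised, and their counts are uncertain to that extent.

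Counts were analysed with R 4.3.3. The low-count filter of edgeR 4.0.16 (filterByExpr, by behavioural type) kept 10948 genes. Library sizes were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 36 libraries with behavioural type and colony as terms, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Further models added DWV load, or the product of type and colony. Genes named were those past the threshold with a mean of at least 4 CPM (counts per 1000000 counts of the library) and the same direction in both colonies (in all 3 types for the colony comparison), the 2 with the greatest log2 change in each direction. Where no gene passed, the genes with the smallest p, at most 3 and a pair per direction, are named as not passing. For the type by colony interaction they are those with the smallest p past the threshold. CPM values use TMM-scaled library sizes, and log2 CPM uses a prior count of 2.

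DWV load was compared between types by two-sided permutation of types within colony (100000 permutations; exact enumeration within a single colony), with adjustment over the 3 pairs of types. These tests and the correlations used Python 3.11.15, SciPy 1.17.1, NumPy 2.4.6 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.

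Library totals over genes ran from 16.2 to 27.5 M (mega) counts. The median standard error of a log2 difference between 2 types was 0.0617, and 90% of genes had one below 0.212 for guards against nurses. Standard errors were computed as the size of the log2 change divided by the square root of the quasi-likelihood test's F statistic. Intervals for genes used these with a quantile of the t distribution. Intervals cover the spread between bees and counting error together. The count model was tested on simulated counts with 50 genes changed at each of 4 sizes, drawn on the means and library sizes of these bees. In the simulated comparison of unresponsive bees with nurses, over 10912 genes, it recovered 62% of genes changed 1.25-fold, 78% at 1.5-fold, 92% at 2-fold and 98% at 4-fold, with 9 false calls, and made 0 calls between guards and nurses, which were simulated without a difference. In the simulated DWV slope, over 10911 genes, it recovered 50% of genes that changed 1.25-fold over 3 log10 units of load. It recovered 92% of those that changed 2-fold, with 7 false calls. All 4 sizes were changed at once, which eases the adjusted threshold, and simulated genes varied independently. Recovery may therefore be lower in a comparison where few genes change.

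Before the comparisons, libraries of the same type were checked for duplicates. No pair among 198 held identical values, and the chi-square per degree of freedom of a pair ran from 9.61 to 99.0, so all libraries were counted as separate bees.

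Alternatives fixed before the data were examined were DESeq2 1.42.0 as the test, its size factors in the edgeR model, no low-count filter, a filter of 1 CPM in 12 libraries, leaving out the 3 libraries numbered 213, a DWV covariate, the number in the bee's title as a block with and without DWV load, no colony term, only the types compared, and each colony alone. For DWV load they were another denominator, ranks, permutation within numbers and each colony alone. The labels say that 6 dishes per colony were used and titles carry 6 numbers per colony, but not that the number marks the dish. Leaving out Guard 210 and Unresponsive 222 was added after seeing the data. Regrouping of the samples used 100 groupings per result, the real one included.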

Results

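Gene expression was measured in brain tissue that held mostly the mushroom bodies from 36 worker honey bees aged 7 days, 12 nurses, 12 guards and 12 unresponsive bees, drawn equally from colony 5 and colony 6. Bees are named here by type and the number in their title. Counts over genes came to 19.3 ± 2.39 M (mega) per library (SD, n = 36) and ranged from 16.2 to 27.5 M. Nurses had 19.9 ± 2.44 M, guards 19.2 ± 2.84 M and unresponsive bees 18.8 ± 1.84 M (SD, n = 12 each).

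Colony was the strongest axis in the data. The first principal component, 21.9% of the variance of log2 CPM, placed all 18 colony 5 libraries between 11.5 and 24.2 and all 18 colony 6 libraries between -28.9 and -11.8. The second, 11.8%, did not separate behavioural types. Colony accounted for a mean of 14.7% of a gene's variance, against 2.86% by chance, and behavioural type for 7.67%, against 5.71% by chance. The title number within colony accounted for 30.3%, against 28.6% by chance. These chance values are means. The median gene had 7.90% for colony, 5.49% for type and 29.5% for number.

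**Figure D1:**
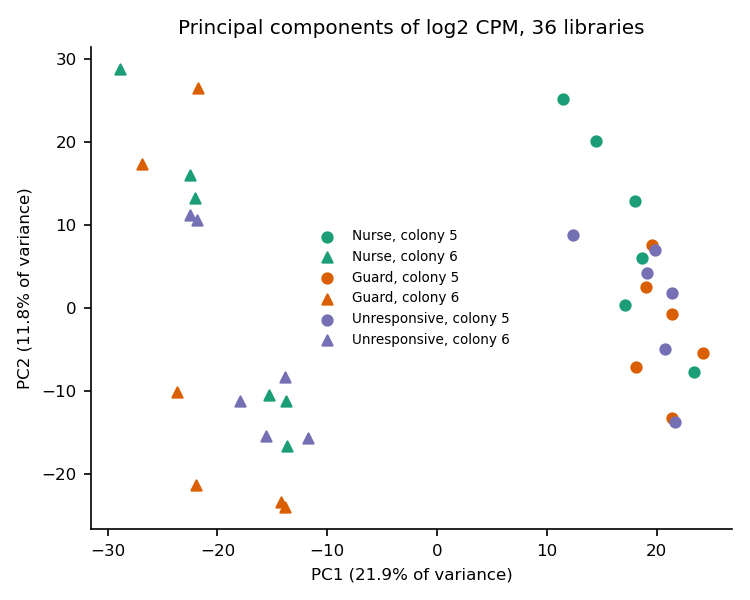
First and second principal components of log2 CPM, one point per library, with colour for behavioural type and shape for colony. The colonies separate on the first component, with colony 5 from 11.5 to 24.2 and colony 6 from -28.9 to -11.8, while the types overlap.

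The first question of the design is whether bees that ignore both social stimuli differ in brain expression from nurses. GB47563 stood at 8.15 ± 13.7 CPM in nurses and 0.806 ± 0.522 CPM in unresponsive bees, with 1.22 ± 0.660 CPM in guards (SD, n = 12 each). GB53371 stood at 9.44 ± 19.6 CPM in nurses and 0.464 ± 0.522 CPM in unresponsive bees. Nurse 210 had the highest value of both, at 49.5 CPM for GB47563 and 70.6 CPM for GB53371, while the median nurse had 8.20 and 7.52 CPM in colony 5 and 1.29 and 1.69 CPM in colony 6. The median colony 6 guard had 1.59 CPM for GB47563 and 0.976 CPM for GB53371. GB53683 stood at 60.6 ± 3.26 CPM in nurses and 66.7 ± 3.73 CPM in unresponsive bees. None of the 3 passed the threshold, with adjusted p of 0.0966 for GB47563 and 0.301 for the others by the edgeR quasi-likelihood test.

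In all, 0 genes differed between unresponsive bees and nurses by edgeR at an adjusted p of 0.05. An unadjusted p under 0.05 was found for 591, against 547 expected by chance. Here and below, that expected count is a mean. Genes vary together, so a count can lie far from it by chance, and its spread was not measured. DESeq2 called 8 genes, 2 higher and 6 lower in unresponsive bees, with adjusted p of 3.13e-05 for GB47563 and 0.0274 for GB53683 and GB53371.

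Guards and nurses, which answered an intruder and a larva respectively, differed in 10 genes, 6 higher and 4 lower in guards. GB42469 stood at 17.6 ± 15.1 CPM in guards and 3.97 ± 2.84 CPM in nurses. The log2 change was 2.09 ± 0.42 (SE), or 4.27-fold with a 95% interval of 2.34 to 7.77. Unresponsive bees stood at 7.29 ± 5.98 CPM. Their mean was 7.28 CPM against 8.37 CPM in guards in colony 5, and 7.29 CPM against 26.9 CPM in colony 6. GB43784 stood at 60.3 ± 55.6 CPM in guards and 18.2 ± 2.1 CPM in nurses, 2.95-fold higher with an interval of 1.85 to 4.71. Its guard mean rested on a few bees: the median guard had 20.9 CPM, Guard 5 had 62.3 CPM, Guard 210, Guard 213, Guard 230 and Guard 237 had 112 to 154 CPM, and no nurse exceeded 22.3 CPM. The mean of unresponsive bees, 19.2 ± 3.03 CPM, lay within 1 SD of that of nurses, and the highest unresponsive bee had 25.1 CPM.

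GB55375 and GB52542 were lower in guards. GB55375 stood at 14.5 ± 5.55 CPM in guards, 26 ± 9.74 CPM in nurses and 22.5 ± 10.6 CPM in unresponsive bees, and fell by 0.92 on the log2 scale from nurse to guard. GB52542 stood at 19.1 ± 5.29 CPM in guards, 27.9 ± 5.41 CPM in nurses and 26 ± 3.53 CPM in unresponsive bees, and fell by 0.56 on the log2 scale. All 4 genes had an adjusted p of 0.0495 by edgeR, just under the threshold. The lowest adjusted p of any gene was 0.00673. With the title number as a block, more genes passed in all, but GB43784 and GB55375 did not.

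Of the 10948 genes tested, 1667 had an unadjusted p under 0.05, against 547 by chance, and 65 had an adjusted p under 0.1. The count was 115 with DESeq2, 1 (a gene that fell) with DESeq2 size factors, without the 3 libraries numbered 213 or without Guard 210 and Unresponsive 222, and 0 in edgeR with DWV load as a covariate, where 617 had an unadjusted p under 0.05. With that covariate the log2 change was 1.48 ± 0.50 (SE) for GB42469 (2.09 ± 0.42 without it), 0.87 ± 0.36 for GB43784 (1.56 ± 0.33), -0.67 ± 0.21 for GB55375 (-0.92 ± 0.19) and -0.47 ± 0.14 for GB52542 (-0.56 ± 0.12).

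Within colony 6 alone 30 genes differed between guards and nurses, 23 higher and 7 lower in guards and 6 of them among the 10 genes, and within colony 5 alone 0 did by edgeR, with 559 at an unadjusted p under 0.05. DESeq2 was not run within single colonies. The difference between the colonies has its own test, given with the interaction. GB43784 had a mean of 95.2 ± 59.6 CPM in colony 6 guards and 25.4 ± 18.1 CPM in colony 5 guards (SD, n = 6 each).

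**Figure D2:**
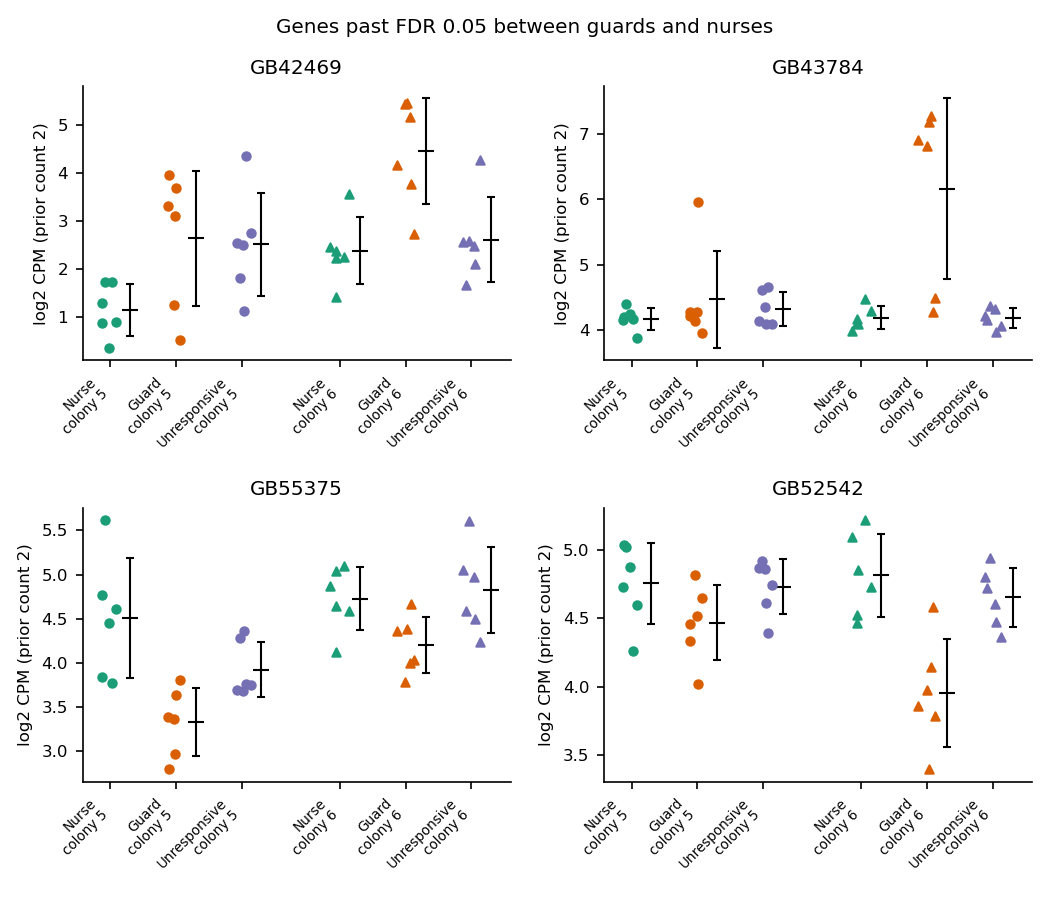
Log2 CPM (prior count 2) of the 4 named genes between guards and nurses, one point per library by type and colony, with bars for mean and SD (n = 6 each). GB43784 is high in 5 of 12 guards, up to 154 CPM, and no nurse exceeds 22.3 CPM.

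Unresponsive bees and guards differed in 2 genes. GB52629 was higher in unresponsive bees, at 21.6 ± 2.40 CPM against 18.5 ± 2.20 CPM in guards, with nurses at 20.6 ± 2.02 CPM (SD, n = 12 each). GB54846 was lower in unresponsive bees, at 17.2 ± 1.70 CPM against 21.5 ± 2.55 CPM in guards, with nurses at 19.3 ± 1.55 CPM. Both changes were small, with log2 differences of 0.23 ± 0.04 (SE) and -0.32 ± 0.06, and both had an adjusted p of 0.0296 by edgeR. At an unadjusted p under 0.05 there were 1715 genes, against 547 by chance. DESeq2 called 105 genes, 35 higher and 70 lower in unresponsive bees, while edgeR called 0 when only unresponsive bees and guards were fitted, with 1432 at an unadjusted p under 0.05, and 24 within colony 6 alone, 0 of them among the 2 genes.

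The contrast closest to the stated theme of the series sets unresponsive bees against the mean of both responsive types. GB54846 had a log2 difference of -0.25 ± 0.05 (SE), and GB50213 one of -0.16 ± 0.04, with 76.3 ± 6.77 CPM in unresponsive bees, 83.6 ± 6.72 CPM in nurses and 87.1 ± 3.34 CPM in guards. Neither passed, both with an adjusted p of 0.344 by edgeR. In all, 0 genes passed by edgeR, 896 had an unadjusted p under 0.05, against 547 by chance, and DESeq2 called 3, all lower in unresponsive bees. Lists of genes by function were not analysed here, because the gene IDs could not be matched to names.

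Colony 6 and colony 5 bees differed in 3737 genes, 1826 higher and 1911 lower in colony 6. Most of these differences were small: the median size among called genes was 0.21 on the log2 scale, and 3188 called genes differed by less than 1.5-fold. A further 237 differed by more than 2-fold, 109 higher and 128 lower in colony 6. In 49 genes every colony 6 bee lay above every colony 5 bee, and in 67 every colony 5 bee lay above every colony 6 bee, and chance gives such an order, in either direction, to a share of 2.2e-10 of genes.

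Some genes were close to present or absent by colony. GB41278 stood at 9.72 ± 1.75 CPM in colony 6 and 0.0316 ± 0.0513 CPM in colony 5 (SD, n = 18 each). GB43966 stood at 13.1 ± 2.13 CPM in colony 5 and 0.210 ± 0.160 CPM in colony 6. GB49219 stood at 85.1 ± 62.0 CPM in colony 5 and 0.0741 ± 0.103 CPM in colony 6, and within colony 5 its libraries were divided between a level of at least 116 CPM in 12 bees and at most 0.311 CPM in 6. GB55212 was called higher in colony 6, but its values ran from 0.618 to 2212 CPM there and from 0 to 301 CPM in colony 5, and it did not pass with DWV load as a covariate. Adjusted p by edgeR was 1.02e-26 for GB41278, 4.31e-25 for GB43966, 9.20e-09 for GB49219 and 0.00618 for GB55212. With DWV load as a covariate the count was 1929, and each colony was a single queen and drone, so that colony stands for family, rearing and any shared handling at once.

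**Figure D3:**
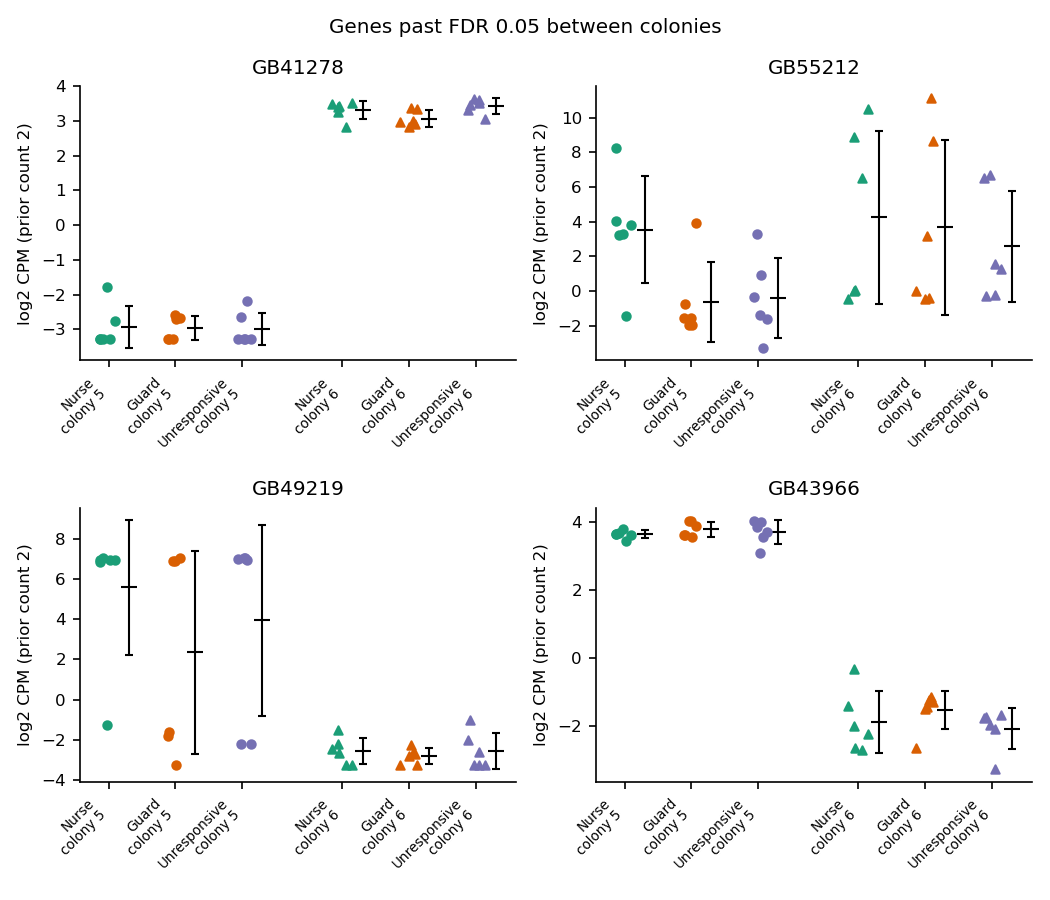
Log2 CPM (prior count 2) of the 4 named genes between colonies, one point per library by type and colony, with bars for mean and SD (n = 6 each). GB41278 and GB43966 separate the colonies completely, while GB49219 is near 116 to 136 CPM in 12 colony 5 bees and at most 0.394 CPM in colony 6.

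For 3 genes the interaction test of edgeR, which asks whether type differences differ between colonies, passed the threshold. An unadjusted p under 0.05 was found for 453 genes, against 547 by chance. Of 100 regroupings, 5 gave at least 3 genes, the real one included, so chance is not excluded for that count. GB53925 stood at 17.8 ± 8.11 CPM in colony 6 guards against 4.63 ± 1.06 CPM in colony 6 nurses, and at 5.23 ± 2.44 CPM against 5.12 ± 2.43 CPM in colony 5 (SD, n = 6 each). GB47805 stood at 173 ± 120 CPM in colony 6 guards against 50.0 ± 5.04 CPM in colony 6 nurses, and at 126 ± 9.23 CPM against 142 ± 15.7 CPM in colony 5. Adjusted p was 0.0323 for GB53925 and 0.0376 for GB47805. GB47545, also at 0.0376, was near the floor in colony 6, with 0 CPM in all 6 unresponsive bees and at most 0.792 CPM in the rest, against 7.31 ± 0.905 CPM in colony 5 (SD, n = 18). By edgeR 0 genes passed with DWV load as a covariate (402 at an unadjusted p under 0.05) or without the 3 libraries numbered 213 (476). The 3 genes also did not pass by edgeR with the title number as a block. DESeq2 called 25 genes with all libraries.

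DWV load, in DWV reads per 1000000 total reads (RPM), fell into a pair of separate ranges. In 16 libraries it was 6673 to 28967 RPM, and in the other 20 it was 2.60 to 63.9 RPM. The higher range held 13 of 18 colony 5 bees and 3 of 18 colony 6 bees. In colony 5 it held all 6 unresponsive bees, 5 of 6 guards and 2 of 6 nurses. In colony 6 it held 3 of 6 guards and 0 of 6 bees of either other type.

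Mean log10 DWV load in RPM was 3.11 ± 1.37 in guards, 2.57 ± 1.76 in unresponsive bees and 1.56 ± 1.36 in nurses (SD, n = 12 each). Guards exceeded nurses by 1.55 (two-sided permutation within colony, p = 0.00671, adjusted p = 0.0201) and unresponsive bees exceeded nurses by 1.02 (p = 0.0234, adjusted p = 0.0351). The difference of unresponsive bees from guards, -0.54, was not past the threshold (permutation p = 0.246).

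The order of types differed between colonies. Within colony 5 alone, the difference in log10 load from nurses was 1.94 for unresponsive bees (exact permutation, adjusted p = 0.0649) and 1.30 for guards (adjusted p = 0.208), and that of unresponsive bees from guards was 0.63 (adjusted p = 0.0649). Within colony 6 alone, the difference from nurses was 1.8 for guards (exact permutation, adjusted p = 0.0357) and 0.0950 for unresponsive bees (adjusted p = 0.652), and that of unresponsive bees from guards was -1.71 (adjusted p = 0.0357). The difference between unresponsive bees and guards was itself 2.34 greater in colony 5 than in colony 6 (permutation, adjusted p = 0.00639), and the corresponding values were 1.84 for unresponsive bees and nurses (adjusted p = 0.0641) and -0.50 for guards and nurses (adjusted p = 0.673).

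**Figure D4:**
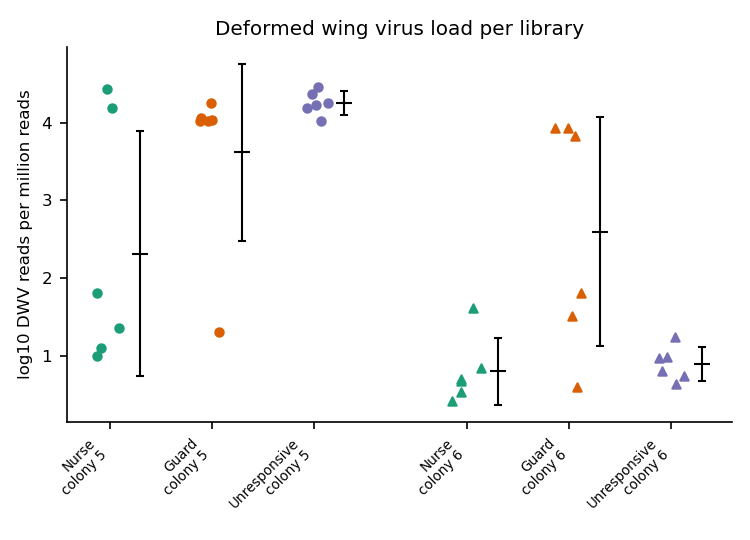
Log10 DWV load in RPM, one point per library by type and colony, with bars for mean and SD (n = 6 each). All 6 unresponsive bees of colony 5 and none of colony 6 lie in the higher range, at 6673 RPM or more.

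Expression was then related to DWV load with type and colony in the model. GB43367 rose by 0.18 ± 0.04 (SE) and GB52829 by 0.19 ± 0.04 on the log2 scale per log10 unit of load, with adjusted p of 0.195 and 0.252 by edgeR, so that neither passed. GB52829 was abundant, at 581 ± 174 CPM over all bees (SD, n = 36). In all, 0 genes passed by edgeR, 479 had an unadjusted p under 0.05, against 547 by chance, and DESeq2 called 12. Without behavioural type in the model 56 genes passed, 43 rising and 13 falling with load.

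The share of reads mapped to neither the bee genome nor DWV rose with the share mapped to DWV. Among the 16 libraries of the higher range, Pearson's r was 0.951 and Spearman's rho 0.926 (both p = 1e-05 by permutation, the smallest that 100000 permutations can give, and 2.5e-05 adjusted over 5 relations), and r was 0.894 without the 2 libraries farthest from the median DWV share. The slope was 2.76 percentage points per percentage point of DWV reads, with a 95% interval of 2.25 to 3.28. Within the 13 of them from colony 5, r was 0.963 and rho 0.951; the 3 from colony 6 are too few. Among the 20 libraries of the lower range, r with log10 load was 0.254 and rho 0.268 (permutation p of 0.290 and 0.252). The DWV share there was at most 0.00639% of reads, and the share mapped to neither had an SD of 1.15 percentage points. A slope of 2.76 could not show at such shares, so the lower range cannot tell whether the relation holds there.

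**Figure D5:**
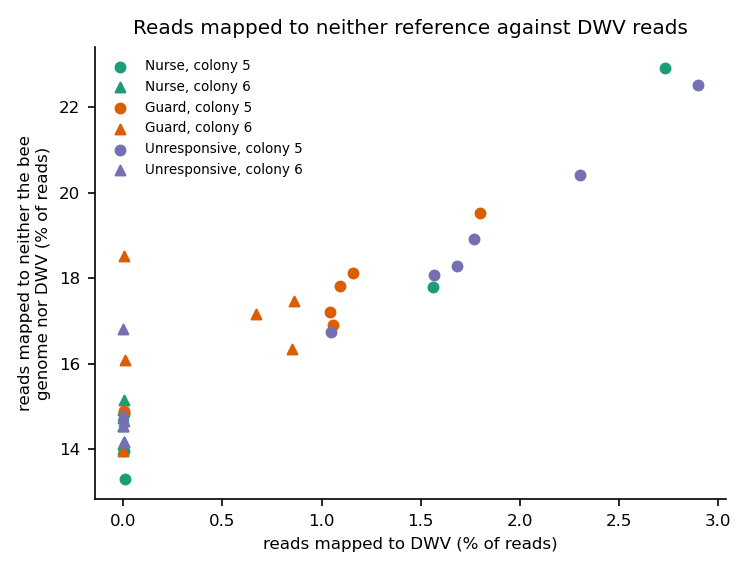
Percentage of reads mapped to neither the bee genome nor DWV against percentage mapped to DWV, one point per library, with colour for type and shape for colony. The share rises with DWV reads at 2.76 percentage points per point in the 16 libraries of the higher range.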

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

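The contrast of guards with both other types, the tests of DWV load on its genes, and the tests of the number of libraries and of depth for GB49219 were chosen only after the result was seen.

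Guards of colony 6 form the first pattern. GB53925 and GB47805, highest on average in colony 6 guards, passed the interaction test of behavioural type by colony, which does not single out guards, with adjusted p of 0.0323 and 0.0376 by edgeR, and GB47545, at 0.0376, was near the floor in colony 6. Counted over 100 regroupings, 5 gave at least 3 interaction genes, the real one included, and the highest of the others gave 9, so chance cannot be excluded for that count. Guards against the mean of nurses and unresponsive bees gave 58 genes over both colonies, and 1 of 100 regroupings gave as many, the real one, the highest other being 12. In colony 6 alone the contrast gave 99 genes, 64 higher and 35 lower, and 2 of 100 regroupings gave as many, the real one included. These shares lie under 0.05, but they do not allow for a contrast chosen from the same data or for the title numbers, so they do not exclude chance. The other of the 2 gave 245 with 3 of the 6 guards in its guard group, so a grouping other than type can also give many genes. What that grouping follows was not tested. In colony 5 alone 0 genes passed by edgeR, with 483 at an unadjusted p under 0.05. Of the 99 genes called in colony 6, 73 had the same direction in colony 5, a count that was not tested. DESeq2 was not run for this contrast.

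The 64 higher genes stood 1.84 to 2.01 log2 units above the nurse mean in Guard 210, Guard 213, Guard 230 and Guard 237, and 0.224 to 0.459 above it in Guard 205 and Guard 222. Whether DWV load acted alike in both colonies was tested on the signed level of the set. Within colony 5 it rose by 0.0432 per log10 unit of load, with a 95% interval of -0.0474 to 0.134. That interval lies below 0.210, which is 0.5 times the colony 6 slope of 0.419. The genes had been chosen for guards in colony 6, where only guards had high load. That choice raises the colony 6 slope, so this comparison cannot decide. Sets were therefore also chosen without each guard in turn. Guard 213, Guard 230 and Guard 237, the guards with high load, stood at 2.18, 2.40 and 0.86 in the sets chosen without them. Per log10 unit of load above the nurses that is 0.697, 0.764 and 0.284. The upper limits of the colony 5 slopes of those sets were 0.228, 0.248 and 0.108. The same ratio was 3.07 for Guard 210, 0.172 for Guard 205 and -0.597 for Guard 222, whose load lay below the nurse mean. Each set was still chosen for the other colony 6 guards, and sets held 40 to 206 genes. These ratios are therefore not slopes on load and cannot decide either. The guards with low load stood at 2.17 (Guard 210, at 32.0 RPM), 0.17 (Guard 205) and 0.12 (Guard 222) in the sets chosen without them, and the highest colony 5 bee for the higher genes was Guard 5, at 0.979. Library depth is argued against, since 95 of the 99 genes stayed called with the library total as a covariate. The 4 guards with high levels had 16.3% to 18.5% of reads mapped to neither reference, against 16.1% in Guard 205, 14.0% in Guard 222, 16.8% in Unresponsive 222 and 14.0% to 15.2% in the other colony 6 bees. They also lay on one side of the second principal component, with 7 nurses and unresponsive bees whose levels were -0.158 to 0.187, low values that the choice of the genes favours. Whether DWV acted alike in both colonies stays undecided. What stays open, untested, is behavioural type within colony 6, DWV acting differently by colony, whatever raises the share of reads mapped to neither reference, a guard effect limited to that side of the second component, and RNA of other cells.

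Reads mapped to neither reference form the second pattern. Their share rose by 2.76 percentage points per percentage point of DWV reads in the higher range. The slope was 3.31, with an interval of 2.80 to 3.81, when the no-feature share, the multi-mapped share and total reads were added. Library depth is thus argued against. Library quality is not settled, because both shares describe aligned reads and cannot register poor reads that fail to align. Unresponsive 222, at 16.8% against 14.2% to 14.8% in the other unresponsive bees of colony 6, stood apart with only 5.40 RPM of reads mapped to DWV. What the reads are, whether DWV that escaped the alignment, another organism or bee RNA, stays open, since the reads themselves were not analysed here.

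GB49219 forms the third pattern. Nurse 5 lay far below the other nurses of colony 5, at -1.27 log2 CPM against 6.86 to 7.08. Over colony 5 the gene was high in 12 of 18 libraries, within the range of 5 to 13 that a chance of 1 in 2 gives in 95% of draws (exact binomial p = 0.238), and high in 5 nurses, 3 guards and 4 unresponsive bees (Fisher's exact p = 0.818). A candidate explanation is an allele of the queen passed to each daughter with that chance, for which the count leaves room but which other causes of 2 levels would meet too. Low depth is argued against, since the libraries near 0 would hold at least 2038 counts at the high level and held at most 5. Reads of a sequence variant that do not align cannot be told apart from absence, because the gene takes 0.00705% of reads and the unaligned share varies by 2.69 percentage points between colony 5 libraries.

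DWV load of unresponsive bees minus guards differed between colonies, with a permutation adjusted p of 0.00639. Within groups of 6, 16 of the 150 sets tested held a library far from the others, where chance gives about 1 in 20. Guard 35 had a log10 DWV load of 1.30 against 4.02 to 4.26 in the other guards of colony 5, and Nurse 205 had 1.62 against 0.415 to 0.847 in the other nurses of colony 6. Guard 213 had 27.5 M counts against 17.4 to 19.9 M, and Nurse 213 had 25.8 M against 18.2 to 20.6 M. Guard 222 had 3.78% multi-mapped reads against 2.86% to 3.07%. On the log2 CPM scale, Guard 5 was high for GB43784 at 5.96, Guard 35 was high for GB55212 at 3.96, Nurse 32 was high for GB53925 at 3.34 and Unresponsive 222 was high for GB42469 at 4.27. GB41278 was at -1.78 in Nurse 5 and 2.84 in Nurse 205, GB43966 at -2.64 in Guard 230 and -3.27 in Unresponsive 237, and GB47545 at -3.27 in Nurse 230, values that except for Nurse 205 lie near the floor.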

How the results depend on the processing

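The alternative that leaves out Guard 210 and Unresponsive 222 was chosen after seeing the data. The count of genes between guards and nurses was 10 by edgeR, and became 1 with DESeq2 size factors (0 higher, 1 lower, against 6 and 4), 1 without the low-count filter, 1 without the libraries numbered 213, 1 without Guard 210 and Unresponsive 222, 0 with DWV load as a covariate (617 at an unadjusted p under 0.05), 6 without the colony term, 0 with only guards and nurses fitted (1645), 0 in colony 5 (559) and 30 in colony 6. Unresponsive bees against guards, 2 genes, gave 4 with DWV load, 0 with only both types fitted (1432), 0 in colony 5 (551), 24 in colony 6 and 4 without Guard 210 and Unresponsive 222. Unresponsive bees against nurses, 0 genes, gave 1 without the colony term. The DESeq2 test called more genes, 8 for unresponsive against nurse, 115 for guard against nurse, 105 for unresponsive against guard, 3 for unresponsive against both, 12 for the DWV slope and 25 for the interaction. The interaction count of 3 became 1 without the filter, 0 without the libraries numbered 213 (476), 0 with DWV load (402) and 1 without Guard 210 and Unresponsive 222. The DWV slope, 0 genes, gave 56 without behavioural type, 1 in colony 5, 1 in colony 6 and 1 without Guard 210 and Unresponsive 222. The colony count of 3737 became 1929 with DWV load, and ran from 3480 to 4057 otherwise. The cause was not tested.

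Same-numbered bees correlated above 0.1 in 21 of 36 pairs (median r 0.126), against 47 of 270 pairs of other numbers in the same colony (median r -0.0756). Of 36 libraries, 14 correlated best with one of their own number. Bees of one number thus tended to be more alike than bees of other numbers. The main fit still left the numbers out, since not all 36 pairs lay above 0.1. Its p-values do not allow for that likeness, and a dish effect is not excluded. With the number as a replicate block the counts were 38 for guard against nurse, 9 for unresponsive against guard and 0 for the interaction (565 at an unadjusted p under 0.05), and with DWV load too 0 (635) and 7 for the first pair. The 38 genes included 7 of the 10, without GB43784 (adjusted p 0.0862 by edgeR) and GB55375 (0.0618), and the 3 interaction genes had 0.0803 to 0.202.

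Differences in DWV load kept direction and side of the threshold under ranks and the other denominator. Permutation within numbers, which cannot change a difference, gave adjusted p of 0.0499 for unresponsive against nurse, 0.0425 for guard against nurse and 0.295 for the other pair. In colony 5 the difference of unresponsive bees from nurses was 1.94 and of guards 1.30, neither past the threshold, and that of unresponsive bees from guards reversed to 0.63. In colony 6 unresponsive bees differed from nurses by 0.0950, not past the threshold, and from guards by -1.71, past it. The cause was not tested. Of the named genes' values, 145 kept their side of the threshold, 61 lost it, 9 gained it and 0 reversed. Gene list and marker tests were not run, as no ID matched a name. In simulated counts 78% of genes changed 1.5-fold were recovered, so smaller changes were not all detectable. For guard against nurse, 2 of 100 regroupings gave at least as many genes (highest other 10). For unresponsive against guard 3 did (highest other 5 against 2), and for colony 1 (highest other 776). No regrouping kept the numbers, whose bees tended to be alike, so these unadjusted shares alone do not exclude chance. For unresponsive against nurse, against both types, and the DWV slope, all with 0 genes, 100 gave as many (highest other 5, 3 and 6), certain with a count of 0 and so no test.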

Other observations

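The search for genes with a pair of levels and the tests of title numbers on principal components were chosen only after the result was seen. A division into high and low libraries within a colony, like that of GB49219, was found in 21 cases over 19 genes, 11 in colony 5 and 10 in colony 6. The criteria were altered once after the data were seen. Each case had a gap of at least 2 log2 units with 3 to 15 libraries above it, an SD of at most 0.5 among those and a mean of at least 4 CPM. One of the colony 6 cases is GB43784, high in 4 guards.

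Within colony 6, bees with the same title number lay together on the first principal component, where 74.1% of the spread lay between numbers (permutation p = 0.00339, adjusted p = 0.0271 over 8 tests, 4 components in each colony). On the second component the share was 62.9% (permutation p = 0.0256, adjusted p = 0.102), and no other test was past the threshold, the lowest adjusted p among them being 0.145. On the second component 11 colony 6 libraries lay below 0 and 7 above it. Those above were all 3 numbered 205, and Nurse 210, Unresponsive 210, Nurse 222 and Guard 222. Guard 210 and Unresponsive 222 lay below 0, and at low DWV load their shares of reads mapped to neither reference were 18.5% and 16.8%.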
